A study of Mus musculus with 16 samples.

How the data were processed

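Single cells were measured from the dorsal lateral geniculate nucleus, the thalamic relay of retinal input, of C57BL/6 mice at postnatal days 5, 10, 16 and 21 (P5, P10, P16 and P21). The series holds 16 samples, 4 per age. Per the labels' protocols, tissue was microdissected from brain slices, digested with proteases, and cells were captured with inDrops, a droplet method that tags each transcript with a cell barcode and a unique molecular identifier (UMI), and sequenced on a NextSeq 500. The labels conflict on the animals behind a sample. They give 8 mice per age as 4 samples of 2 mice, and also a pool of 4 animals per replicate with 2 libraries collected from each sample.

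The deposited values are raw UMI counts per cell barcode and gene, with no normalisation: all of them were whole numbers in 25289 gene columns shared by the 16 files. Per the submitters' processing notes, reads were aligned with Bowtie 1.1.1 to GRCm38, and per the deposited settings file RSEM 1.2.25 and SAMtools 1.3.1 were used and the libraries were spread over 6 sequencing runs. That settings file names samples 1 and 2 of P10 and of P16 in the first 2 runs. It names the other 12 libraries in a way that ties them to no sample. Everything from here on was computed from the counts, and the markers, gene lists, planned comparisons and their tests, and the rule for genes to name were fixed before the data were examined. Chosen later were the comparison of oligodendrocyte-like cells between P21 and P10, the share of doublets removed, the sums of pairs, the fits with 1 pair per age, the tests of differences between classes, the addition of barcodes above 15000 UMIs and some tests of explanations.

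Barcodes with 500 to 15000 UMIs and a mitochondrial share of at most 20% were kept, which left 61366 of 146982 barcodes. The mitochondrial limit removed 12497 barcodes, between 2.43% and 33.2% of those in the UMI range of a sample, and 2316 barcodes lay above 15000 UMIs. Doublet scores came from Scrublet as implemented in scanpy 1.11.5. The automatic threshold called from 0% to 7.71% of the cells of a sample, so the 5% with the highest scores were removed from each sample, 3071 in all, and 58295 cells remained. Cells were scaled to equal totals, log-transformed, and clustered with the Leiden method (leidenalg 0.10.2, resolution 1) on a graph of 15 neighbours from 2000 variable genes and 40 principal components. This gave 43 clusters. A cluster was named after 1 of the cell type marker lists (19 lists) when at least 50% of its markers were detected, unless over 40% of its cells were predicted doublets (7 clusters) or the markers of a second class were raised too (2 clusters), and the names therefore mean "like" that type. Names went to 43028 cells in 14 classes. In 14 clusters no name was given, and 3 of these, with 13582 cells, had the profile of the free RNA of their samples as read from barcodes of at most 300 UMIs. A doublet whose members are of 1 type stays undetected by this method.

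Counts were summed per sample and class, and a sample entered with at least 10 cells of the class. Genes were tested with edgeR 4.0.16 (TMM factors, filterByExpr, robust quasi-likelihood F test) in 1 fit per class over all ages with a coefficient per age. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as a change. Fold changes are log2 values with their standard error (SE), and levels are CPM, the counts of a gene divided by all counts of the class in the sample, without size factors, as mean ± standard deviation (SD) of 4 samples. Gene lists (24 lists, 481 entries) were tested against the other genes of a class with camera of limma 3.58.1 on voom values, with the correlation between genes preset to 0.01, where at least 5 members were measured. Each list call was repeated with the correlation estimated from the data and with fry. The share of each class at P21 and P5 was compared by a two-sided exact permutation test over 70 arrangements, adjusted over the 14 classes. Intervals on shares are Wilson 95% intervals. Intervals and floors cover counting error only.

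Genes named in the text were taken by rule. For excitatory neuron-like cells between P21 and P5 these were the 8 largest rises and the 8 largest falls, for other classes the 5 largest each way, and for the steps between successive ages the 3 largest each way. They had to be called, to have a mean of at least 50 CPM, to keep their sign when any sample was left out, and to reach 0.2 of the highest level in any other tested class, since a lower level could be RNA from that class; gene models without a symbol and mitochondrial genes were passed over. From each list up to 4 members in excitatory neuron-like cells and 3 in other classes were added, called or not, those with the smallest adjusted p. Some of the genes that the rule names are not reported here. Positions of named genes are from the GENCODE annotation of GRCm38.

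The pipeline was tested on simulated data, negative binomial counts with the means, depths and dispersions of each class and 200 genes changed at P21. For excitatory neuron-like cells 52 of 100 genes changed by 1 log2 unit were recovered and 89 of 99 changed by 2 units, with 5.37% false calls. Over the 8 classes simulated the false calls were 1.19% to 9.24%. For microglia-like cells the recovered shares were 13.7% and 85.3%. In each simulated class 5 of 5 raised lists and 0 of 45 others were called. Genes and samples were simulated as independent. The simulation therefore cannot tell how many false calls correlated genes or samples that resemble each other would give.

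Samples 1 and 2 of an age resembled each other, and so did samples 3 and 4, more closely than samples of different pairs. If each pair holds libraries of 1 pool, the number of independent pools is 2 per age and the p-values of the 16-sample fits are too small. The SEs, the SDs with n = 4 and the list and share tests would then rest on 2 pools per age too. For this reason every count of changed genes is also given with each of these pairs summed to 1 sample, an alternative chosen after seeing the data. A second check asked whether equal replicate numbers of different ages belong together. Between P21 and P5 no class showed this, with correlations of -0.0683 to 0.0127 in excitatory neuron-like cells. For astrocyte-like cells between P16 and P10 every correlation was above 0.1, and with the replicate number as a block 1470 genes were called there in place of 1371.

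Alternatives were run for the size factors (RLE), the test (DESeq2 1.42.0), the gene filter, a minimum of 1000 UMIs per cell, kept doublets, ages in the fit, replicate block, a term for the libraries named in the first 2 runs, genes that could be free RNA, each sample left out, the clustering resolution and the denominator of shares. Inhibitory neuron-like cells, and oligodendrocyte-like cells at P5, were too few for a gene test. Python 3.11.15 and R 4.3.3 were used.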

Results

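Gene expression was measured in single cells of the mouse dorsal lateral geniculate nucleus at P5, P10, P16 and P21, with 4 samples at each age, across the weeks in which retinal inputs to this nucleus are sorted and pruned. The files held 5123743 to 36932773 UMIs per sample, and the kept cells had a median of 1051 to 2913 UMIs per sample. Samples 1 and 2 of each age were closer to each other than to samples 3 and 4, and the same held for samples 3 and 4. In excitatory neuron-like cells the median chi-square per gene, divided by the value that counting error alone gives, was 1.17 to 2.72 within these pairs and 2.56 to 12 between them.

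**Figure D1:**
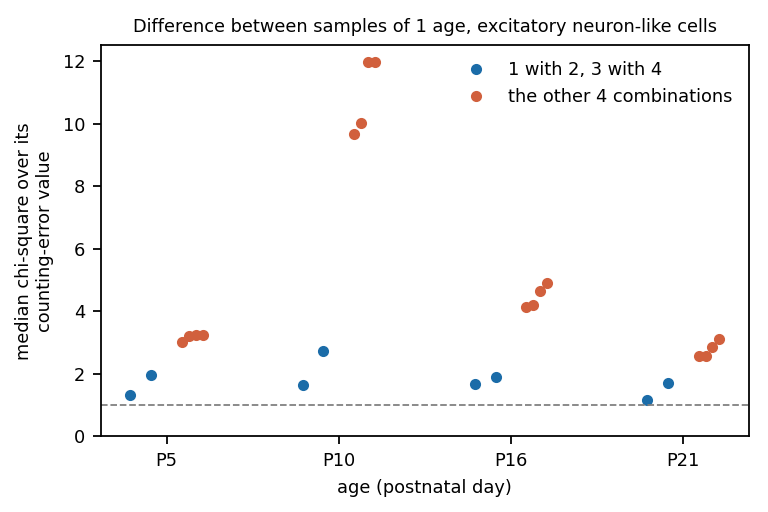
Difference between any pair of samples of 1 age in excitatory neuron-like cells, as the median chi-square per gene over its counting-error value (y axis, ratio; the dashed line at 1 is counting error alone) at each age (x axis). Each point is 1 combination of samples, and at every age the points for samples 1 with 2 and 3 with 4 lie below those of the other combinations.

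The first comparison asked what share of the cells kept at each age belonged to each class. These cells came through dissociation, capture and the filters, so their shares are not the makeup of the tissue. In the UMI range the mitochondrial limit removed 25.3% to 33.2% of barcodes at P5 and 2.43% to 18.5% at P21. Oligodendrocyte-like cells, which form myelin, made up 0.0174% ± 0.0137 (SD, n = 4) of cells at P5, with 3 cells in all, and 37.2% ± 23.1 at P21, after 1.35% ± 0.841 at P10 and 14.4% ± 7.24 at P16. Oligodendrocyte precursor-like cells (OPC-like) were most frequent at P10, 26.4% ± 2.79, and lower at P21 than at P5, 4.14% ± 2.41 against 14.4% ± 4.75. Committed oligodendrocyte-like cells, the stage between, went from 2.97% ± 0.102 at P5 to 11.6% ± 0.503 at P10 and 6.85% ± 3.40 at P21. Excitatory neuron-like cells, the relay neurons' class, were 14.3% ± 2.25 of cells at P5 and 6.48% ± 3.21 at P21 (with barcodes above 15000 UMIs added, 21.7% ± 2.06 at P5, 20.1% ± 0.699 at P10, 12.2% ± 4.94 at P16 and 6.55% ± 3.15 at P21), and inhibitory neuron-like cells 1.13% ± 0.811 and 0.0797% ± 0.0942, the latter from 9 cells. Fibroblast-like or meningeal-like cells went from 2.13% ± 0.795 to 0.452% ± 0.307. At P21 samples 1 and 2 differed from samples 3 and 4: oligodendrocyte-like cells were 12.4% and 22.5% against 56.5% and 57.2%, astrocyte-like cells 6.70% and 13.3% against 1.48% and 2.37%, and excitatory neuron-like cells 2.88% and 4.66% against 9.31% and 9.07%. The denominator holds cells in clusters with the profile of free RNA, 53.45%, 9.16%, 5.27% and 0.5% of P21 samples 1 to 4. Differences in share between samples 1 and 2 are not separated from this.

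In these 5 classes (oligodendrocyte-like, OPC-like, excitatory neuron-like, inhibitory neuron-like and fibroblast-like) every P21 sample lay on 1 side of every P5 sample, with the smallest p that 70 arrangements allow, 0.0286 (two-sided exact permutation test), and an adjusted p of 0.08 over 14 classes, so 0 of 14 classes passed the adjustment. All classes of a sample have 1 denominator, so the rise of oligodendrocyte-like cells by itself lowers the shares of the others. Lower shares at P21 are not separated from this. Astrocyte-like cells were 16.1% ± 5.98 at P5 and 5.97% ± 5.42 at P21 (exact p = 0.0857), endothelial-like cells 6.79% ± 1.60 and 11.5% ± 5.17 (exact p = 0.0571), and pericyte-like cells 3.72% and 1.44% (exact p = 0.0571). Microglia-like cells were 3.21% and 2.15%, macrophage-like cells 0.739% and 0.560%, smooth muscle-like cells 1.57% and 1.95%, erythroid-like cells 1.46% and 2.00%, and lymphocyte- or granulocyte-like cells 0.0805% and 0.153%. With the neurons taken out of the denominator 12 classes were tested and 7 passed the adjustment over these 12. Clusters with the profile of free RNA held 26.0% of cells at P5, 10.3% at P10, 29.4% at P16 and 22.3% at P21 (per sample 23.66% to 27.56%, 7.85% to 14.49%, 1.24% to 49.49% and 0.5% to 53.45%), and with pairs summed the smallest possible p is 0.333.

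**Figure D2:**
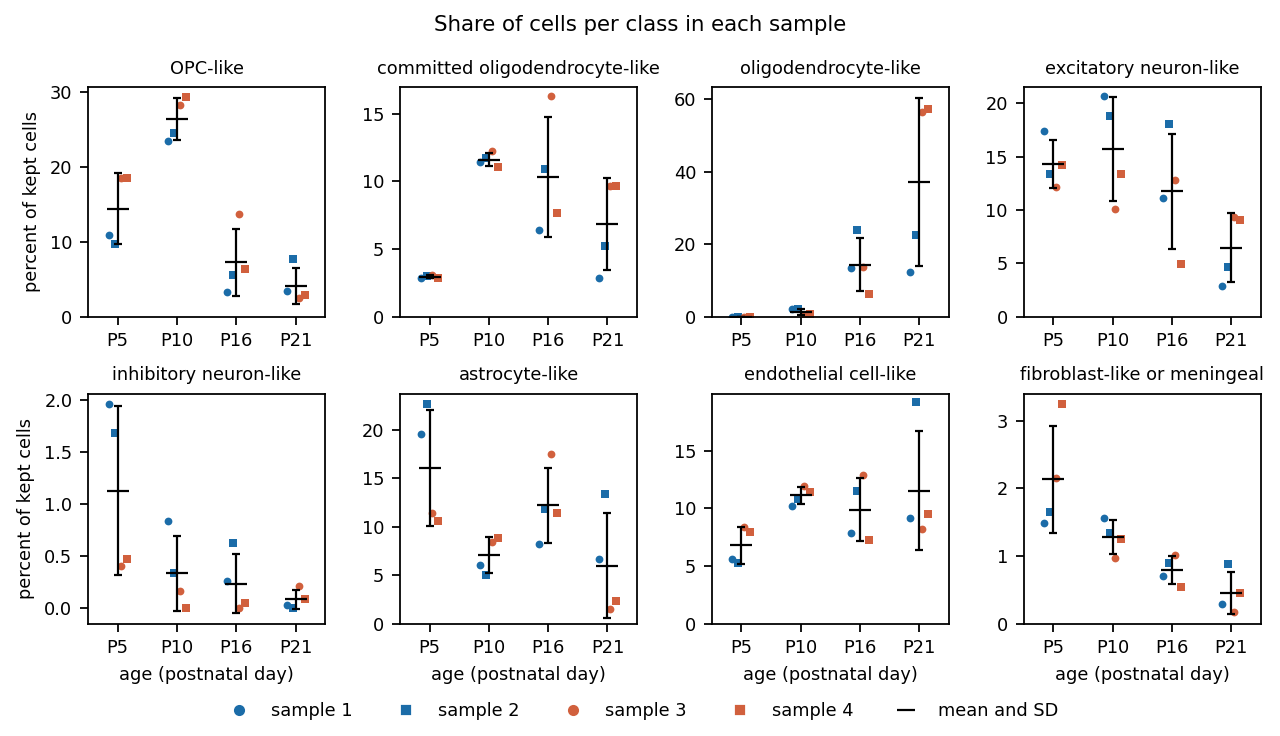
Percent of kept cells (y axis) in 8 classes at each age (x axis). Each point is 1 sample, the bar and whiskers are mean and SD of 4 samples, and the 4 oligodendrocyte-like values at P21 run from 12.4% to 57.2%.

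In excitatory neuron-like cells a set of immature genes was lower, and a set of mature relay neuron genes higher, at P21 than at P5. Gabrd, the delta subunit of extrasynaptic GABA-A receptors (chromosome 4, 155384980 to 155398112, GRCm38), rose by 8.98 ± 0.32 (SE) on the log2 scale, from 0.443 ± 0.229 to 218 ± 53.4 CPM (SD, n = 4). Prkcd, a protein kinase C that marks these neurons (chromosome 14, 30595354 to 30626210), rose by 7.52 ± 0.30, from 14.5 ± 0.867 to 2671 ± 223 CPM. Slc18a2 (chromosome 19, 59260896 to 59296012) and Slc6a4 (chromosome 11, 76998603 to 77032340), transporters that load serotonin into vesicles and take it up from outside the cell, went from 522 ± 97.3 to 1.49 ± 1.16 CPM and from 248 ± 22.4 to 0.856 ± 0.988 CPM, for Slc6a4 331 times lower in summed counts (95% interval 91.7 to 2736). St8sia2, which makes polysialic acid, was 692 times lower (interval 124 to 27350), and the microtubule proteins Tubb2b and Dcx of young neurons fell by 6.99 ± 0.49 and 5.86 ± 0.25.

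Of 11946 genes tested, 5399 changed, 2765 of them higher at P21 and 2634 lower, and 3430 changed with the pairs summed. The other genes with the largest rises were Ramp3, by 6.57 ± 0.18, Rasgrp1 (6.32 ± 0.24), Rab37 (5.85 ± 0.19), Slc9a3r1 (5.55 ± 0.23), the histamine receptor gene Hrh3 (5.32 ± 0.25) and Ptk2b (5.05 ± 0.23). The others with the largest falls were the cell cycle inhibitor Cdkn1c, by 7.53 ± 0.52, Sbk1 (7.09 ± 0.36) and Nnat (6.30 ± 0.25). Adjusted p-values of the genes named so far ran from 7.0e-16 to 3.0e-09.

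As lists, immature neuron genes fell and channels of mature firing and vesicle release genes rose, while synaptic adhesion genes fell. Of 21 neurite growth and immature neuron genes 19 fell and 2 were not called (20 adjusted over the list alone), with a median of -2.42 and an adjusted p of 3.3e-17. Nrep fell by 4.57 ± 0.17 and Dpysl3 by 4.52 ± 0.15. Of 26 channels of mature firing 18 rose and 5 fell (23 adjusted over the list alone, median 1.74, adjusted p = 1.6e-06). The sodium channel subunit Scn4b rose by 5.55 ± 0.33 and the potassium channel Kcna1 by 3.37 ± 0.23. Of 22 vesicle release genes 14 rose and 2 fell (16 adjusted over the list alone, median 0.63, adjusted p = 0.000249). Snap25 of the fusion complex rose by 2.94 ± 0.14 and Vamp1 by 3.34 ± 0.19, while Stx1a, another member, fell by 4.16 ± 0.24. Of 27 synaptic adhesion genes 7 rose and 16 fell (24 adjusted over the list alone, median -0.72, adjusted p = 0.0427), and the list had adjusted p = 0.169 with an estimated correlation. Lrrtm2 rose by 2.25 ± 0.20, Cntnap2 fell by 1.39 ± 0.13, and Cbln2 was 63.8 times lower in summed counts (interval 17.6 to 528).

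Some receptor subunits rose and others of the same families fell, without a call for either family as a list. Of 14 GABA-A receptor and chloride transporter genes 5 rose and 6 fell (11 adjusted over the list alone, adjusted p = 0.974, median -0.35 with a mean of 0.09). Gabrd and Gabra4 rose, the latter by 4.52 ± 0.15, and Gabra3 and Gabra2 fell by 4.87 ± 0.35 and 3.08 ± 0.24. Of 20 glutamate receptor genes 5 rose and 8 fell (13 adjusted over the list alone, adjusted p = 0.145). The AMPA receptor subunit Gria3 rose by 3.09 ± 0.25 and Gria2, Grik3 and Grm5 fell by 2.01 ± 0.14, 3.15 ± 0.19 and 2.10 ± 0.20. Of 31 axon guidance genes 6 rose and 11 fell (17 adjusted over the list alone, adjusted p = 0.0981), with Robo2 lower by 4.53 ± 0.24 log2 units and Ncam1 by 3.16 ± 0.19.

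As lists, respiratory chain and glycolysis genes rose in these neurons, and ribosomal protein and cholesterol synthesis genes fell. Of 22 nuclear-encoded respiratory chain genes 20 rose and 0 fell (21 adjusted over the list alone, median 0.96, adjusted p = 4.7e-09). Cox7b rose by 1.67 ± 0.17 and Uqcrb by 1.64 ± 0.15. Of 16 glycolysis genes 12 rose and 2 fell (14 adjusted over the list alone, median 1.38, adjusted p = 9.9e-05). Ldhb rose by 2.65 ± 0.16 and Eno2 by 2.21 ± 0.13. Of 27 cytosolic ribosomal protein genes 25 fell (25 adjusted over the list alone, median -0.89, adjusted p = 4.4e-10), and the list had adjusted p = 0.102 with an estimated correlation. In free RNA the same list, summed, fell by 1.35. Of 16 cholesterol synthesis genes 10 fell and 6 were not called (13 adjusted over the list alone, median -0.86, adjusted p = 0.000262). Not called as lists were cell cycle (2 of 14 fell, 2 adjusted over the list alone), heat shock (4 of 12 rose and 1 fell, adjusted p = 0.473) and immediate early genes, which follow neuronal activity (5 of 18 rose and 2 fell, 7 adjusted over the list alone, adjusted p = 0.201), of which Nptx2 rose by 3.60 ± 0.37. Genes typical of oligodendrocytes took 0.0286% ± 0.00307 of the UMIs of these cells at P5 and 0.154% ± 0.0162 at P21, and without the genes whose level could be free RNA 4432 genes changed. The class lay in cluster 8 at P5, clusters 17 and 23 at P10 and mainly cluster 5 at P16 and P21. Its cells of different ages thus shared few clusters. A change in the makeup of excitatory neuron-like cells is therefore not separated from a change within them.

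**Figure D3:**
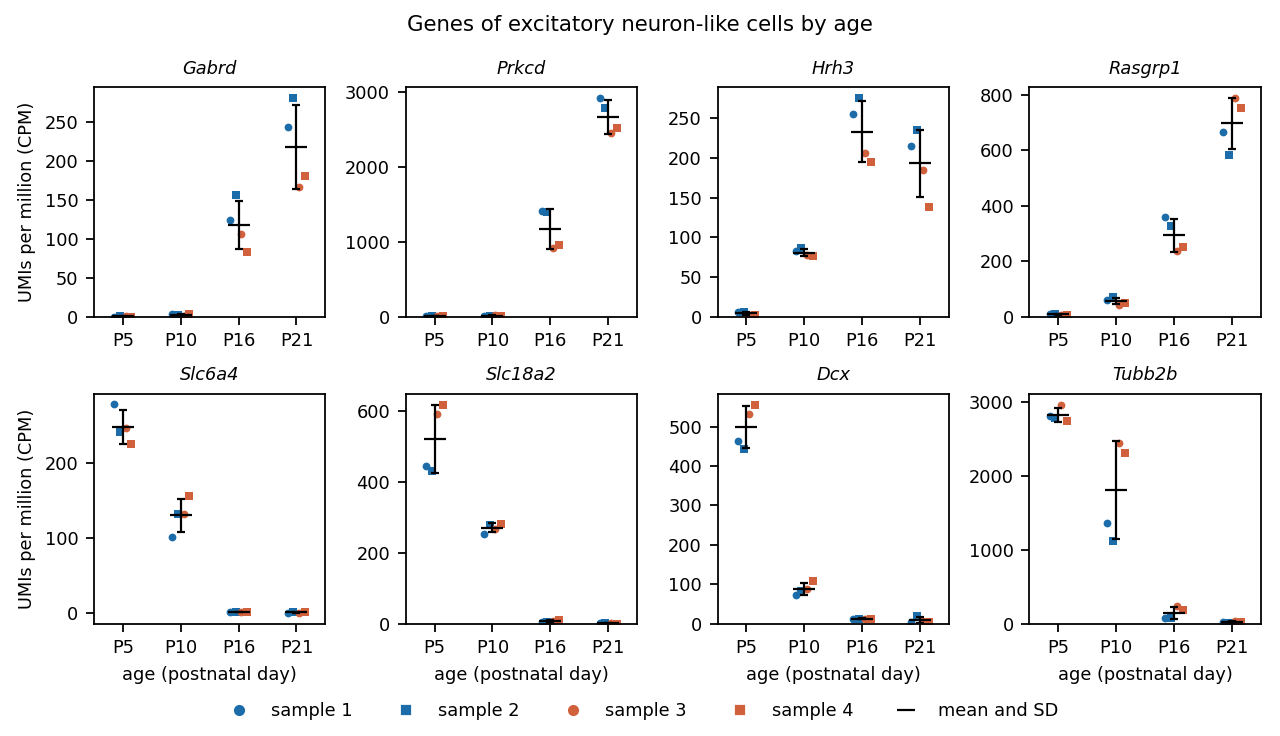
CPM (y axis) of 8 genes in excitatory neuron-like cells at each age (x axis). Each point is 1 sample and the bar and whiskers are mean and SD of 4 samples; Gabrd and Prkcd are low until P10 and high from P16, and Slc6a4 and Slc18a2 are near 0 from P16.

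Between P10 and P5, the step that ends before the eyes open, Hrh3 rose by 4.09 ± 0.24, Car7, a carbonic anhydrase, by 3.28 ± 0.22 and Slc9a3r1 by 2.96 ± 0.23 in excitatory neuron-like cells. St8sia2 fell by 3.27 ± 0.27, Dcx by 2.51 ± 0.18 and Trp53i11 by 1.96 ± 0.20. Of 11946 genes 1864 changed, 1066 higher and 798 lower at P10, and 193 changed with the pairs summed, when these 6 genes kept adjusted p-values of 0.00106 to 0.00979.

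Between P16 and P10, the step that spans eye opening, Prkcd rose by 6.83 ± 0.30, Gabrd by 5.48 ± 0.26 and Ramp3 by 4.74 ± 0.17. Slc6a4 fell by 6.51 ± 0.24, to 1.39 ± 0.114 CPM from 130 ± 22.5, Slc18a2 fell by 5.57 ± 0.27, and St8sia2 by 5.96 ± 0.50. In all 3441 genes changed, 1580 higher and 1861 lower at P16, and 1201 with the pairs summed.

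Between P21 and P16 the calcium-binding protein gene Calb2 (chromosome 8, 110137502 to 110168210) fell by 5.08 ± 0.24, from 598 ± 114 to 18.3 ± 3.83 CPM, Cdkn1c by 4.32 ± 0.63 and Smyd1 by 3.04 ± 0.39. Spock3 rose by 1.58 ± 0.19 and Cttnbp2 by 1.46 ± 0.17. In all 932 genes changed, 372 higher and 560 lower at P21. The count was 570 without P16 sample 3 and 43 with the pairs summed. Of the 6 genes that the rule names for this step 5 were called with the pairs summed.

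In astrocyte-like cells a list of astrocyte maturation genes rose and cell cycle genes fell between P5 and P21. Etnppl, an astrocyte enzyme of phospholipid breakdown (chromosome 3, 130617448 to 130637521), rose by 9.89 ± 0.36, from 0.605 ± 0.729 to 779 ± 90.1 CPM, Fam107a by 8.41 ± 0.49, and Gjb6, the gap junction protein connexin 30, by 6.49 ± 0.27. The filament gene Vim fell by 4.63 ± 0.32 and the matrix genes Tnc and Ncan by 4.53 ± 0.32 and 2.74 ± 0.21. Apln (6.76 ± 0.35) and Cd38 (6.67 ± 0.39) rose too, and Nsg2, Tnfrsf21 and Fxyd6 fell by 4.99 ± 0.36, 4.78 ± 0.57 and 4.19 ± 0.46. Of 8279 genes tested 2629 changed, 1115 higher and 1514 lower at P21, and 1300 with the pairs summed.

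Of 19 astrocyte maturation genes 16 rose and 1 fell (17 adjusted over the list alone, median 2.30, adjusted p = 1.8e-16). Glul, which makes glutamine from glutamate, rose by 2.65 ± 0.19 and Ntsr2 by 3.38 ± 0.24. Of 17 cell cycle genes 15 fell and 0 rose (16 adjusted over the list alone, median -2.57, adjusted p = 9.5e-07). Ccnd2 fell by 2.75 ± 0.34 and Tpx2 by 2.57 ± 0.47. Of 17 matrix, synaptogenic and phagocytic genes 10 rose and 3 fell (14 adjusted over the list alone, median 1.44, adjusted p = 0.000855), with Gpc5 up by 3.67 ± 0.29. Of 15 glycolysis genes 11 rose (11 adjusted over the list alone, median 1.46, adjusted p = 4.2e-07). Aldoc rose by 3.18 ± 0.24, and the list had adjusted p = 0.11 with an estimated correlation. Of 22 respiratory chain genes 10 rose and 1 fell (14 adjusted over the list alone, median 0.57, adjusted p = 0.000354). Cycs rose by 1.74 ± 0.28, and the list had adjusted p = 0.352 with an estimated correlation. Of 27 ribosomal protein genes 25 fell (26 adjusted over the list alone, median -1.28, adjusted p = 4.6e-14). Rps2 fell by 2.18 ± 0.25. Of 16 immediate early genes 9 fell and 1 rose (12 adjusted over the list alone, median -1.42, adjusted p = 0.0119). Nr4a1 fell by 3.19 ± 0.51 and Egr1 by 1.81 ± 0.42, and the list had adjusted p = 0.352 with an estimated correlation and 0.121 without the genes that could be free RNA. Not called were cholesterol synthesis (3 of 16 rose and 2 fell, adjusted p = 0.442), where Msmo1 rose by 1.87 ± 0.18 and Hmgcs1 fell by 1.41 ± 0.19, complement and phagocytosis (2 of 5 rose, Mertk by 1.89 ± 0.29, adjusted p = 0.0513), antigen presentation (1 of 5 rose, adjusted p = 0.0549) and heat shock (1 of 12 rose and 1 fell, adjusted p = 0.330). Oligodendrocyte genes took 0.0656% ± 0.0057 of UMIs at P5 and 0.597% ± 0.158 at P21, and genes of any neuron 0.194% ± 0.0938 and 0.0499% ± 0.0137. The class lay in clusters 10 and 16 at P5 and cluster 6 at P16 and P21. Clusters 10 and 16 each held 1 cell at P21, and cluster 6 held 0 cells at P5. A change in the makeup of astrocyte-like cells between P5 and P21 is therefore not separated from a change within them.

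Between P10 and P5 astrocyte-like cells gained Apln, a peptide signal, by 4.92 ± 0.36, Fam107a by 3.98 ± 0.52 and Acot11 by 3.06 ± 0.32, while the signalling inhibitor Socs3 fell by 1.82 ± 0.36 and Hn1 by 1.51 ± 0.22. In all 571 genes changed, 352 higher and 219 lower at P10, and 42 with the pairs summed, when Socs3 (adjusted p = 0.128), Hn1 (0.0602) and Nr4a1 (0.720) were not called. In this step 352 changed without P10 sample 3 and 319 without P10 sample 4. Nr4a1 fell by 1.60 ± 0.44 and lost its call when any 1 of the 8 samples was left out.

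Between P16 and P10 Etnppl, with 0 counts at P10, was at least 303 times higher (floor of 3 counts over the age) and reached 575 ± 78.7 CPM, Hr, a transcriptional regulator, rose by 5.09 ± 0.41 and Fam107a by 4.77 ± 0.40. Myoc (chromosome 1, 162639155 to 162649693) fell by 8.17 ± 1.11, from 642 ± 221 to 2.13 ± 1.53 CPM, Gfap, the main filament of fibrous astrocytes, by 4.45 ± 0.34 and Fxyd6 by 5.10 ± 0.49. In all 1371 genes changed, 600 higher and 771 lower at P16, and 398 with the pairs summed. The class lay in clusters 10, 16 and 30 at P10 (414, 185 and 158 cells) and cluster 6 at P16 (2038 cells). Cluster 16, with Gfap and Myoc among its top genes, held 1 cell at P16, so a change in the makeup of the class is not separated from a change within its cells.

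Between P21 and P16 few genes separated astrocyte-like cells. Fdft1, which makes squalene on the way to cholesterol, rose by 1.40 ± 0.21, Mgst1 by 1.62 ± 0.30 and Aacs by 1.57 ± 0.30, and Frmpd1, Kcnq3 and Pla2g3 fell by 1.63 ± 0.27, 1.63 ± 0.28 and 1.63 ± 0.28. Of 8279 genes 40 changed, 19 higher and 21 lower at P21. With the pairs summed edgeR called 0 genes and 507 had an unadjusted p under 0.05, while on the 16 samples DESeq2 called 102. The edgeR count was 14, 20 and 24 without P21 sample 1, P21 sample 2 and P16 sample 3, and 144 with the replicate number as a block.

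In OPC-like cells Neu4, a sialidase (chromosome 1, 94020451 to 94028334), rose by 4.97 ± 0.19 between P5 and P21, from 30.0 ± 8.49 to 1018 ± 107 CPM, S100b, a calcium-binding protein of glia, by 3.09 ± 0.18, Col11a2 by 3.40 ± 0.31, Ifitm10 by 3.07 ± 0.24 and the potassium channel Kcnk3 by 3.04 ± 0.36. Rbm3 fell by 2.36 ± 0.25, Trim37 by 2.05 ± 0.29, the ribosomal gene Rplp0 by 1.99 ± 0.18, Cdkn1c by 1.97 ± 0.45 and Hes5, an effector of Notch, by 2.85 ± 0.78. Of 10397 genes 1558 changed, 792 higher and 766 lower at P21, 952 without P21 sample 2, and 397 with the pairs summed, when Hes5 (adjusted p = 0.106) and Cdkn1c (adjusted p = 0.0588) were not called.

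Of 27 ribosomal protein genes 23 fell in OPC-like cells (25 adjusted over the list alone, median -1.02, adjusted p = 6.4e-23). Of 12 myelin genes 7 rose (11 adjusted over the list alone, median 3.54, adjusted p = 8.7e-10), and the list had adjusted p = 0.11 with an estimated correlation. Oligodendrocyte genes took 0.133% ± 0.008 of the UMIs of these cells at P5 and 0.467% ± 0.0601 at P21, and free RNA is not excluded as a source of the myelin rise. Of 16 cholesterol synthesis genes 8 fell (8 adjusted over the list alone, median -0.85, adjusted p = 3.7e-06), and the list had adjusted p = 0.11 with an estimated correlation. Of 13 immediate early genes 5 rose (5 adjusted over the list alone, median 0.31, adjusted p = 0.00176). Jund rose by 1.48 ± 0.22, and the list had adjusted p = 0.11 with an estimated correlation. Of 21 cell cycle genes 4 fell and 1 rose (6 adjusted over the list alone, median -0.42, adjusted p = 0.0107), Mcm5 down by 1.37 ± 0.32 and Ccnd1 up by 1.39 ± 0.20, and the list had adjusted p = 0.449 with an estimated correlation. Of 15 glycolysis genes 3 rose (3 adjusted over the list alone, median 0.46, adjusted p = 0.0107). Aldoa rose by 1.40 ± 0.34, and the list had adjusted p = 0.169 with an estimated correlation. Respiratory chain (4 of 22 fell, adjusted p = 0.0745) and heat shock (1 of 12 rose, adjusted p = 0.849) were not called. Of 17 called list members that the rule names in this class 5 were called with the pairs summed. Clusters 2 and 18 held the class at every age. Cluster 18, with Top2a as its first top gene, held 584 of 2271 cells at P5 and 46 of 430 at P21. At the higher clustering resolution the class split by age. There cluster 2 held 1648 cells at P5 and 35 at P21. Cluster 10, with Neu4 among its top genes, held 42 and 347. A change in the makeup of OPC-like cells is therefore not separated from a change within them, for Neu4 and cell cycle genes too.

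Committed oligodendrocyte-like cells of P21 carried far more myelin and cholesterol synthesis transcripts than those of P5. Mobp, a myelin protein (chromosome 9, 120149707 to 120181484), rose by 10.10 ± 0.51, from 3.28 ± 3.32 to 3462 ± 552 CPM, and Tmem2 by 8.66 ± 0.39, and Cldn14 and S1pr5 were 190 (interval 33.6 to 7542) and 147 (interval 50 to 718) times higher in summed counts. All 13 myelin genes rose (13 adjusted over the list alone, median 4.17, adjusted p = 6.3e-17). Mag rose by 4.17 ± 0.23. All 16 cholesterol synthesis genes rose (16 adjusted over the list alone, median 1.44, adjusted p = 5.0e-13). Dcx fell by 4.78 ± 0.41, Cbln2 by 3.70 ± 0.40, Cdkn1c by 3.63 ± 0.27, Mex3a by 3.11 ± 0.39 and Gpm6a by 3.04 ± 0.33. Of 9209 genes 3083 changed, 1593 higher and 1490 lower at P21, and 1628 with the pairs summed.

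Of 27 ribosomal protein genes 26 fell in this class (26 adjusted over the list alone, median -1.15, adjusted p = 3.8e-18). Rps4x fell by 1.81 ± 0.18, and the list had adjusted p = 0.05001 with an estimated correlation. Of 22 respiratory chain genes 7 fell and 1 rose (10 adjusted over the list alone, median -0.26, adjusted p = 0.0293), Ndufa5 down by 0.99 ± 0.21, and the list had adjusted p = 0.381 with an estimated correlation and 0.0659 with the pairs summed. Not called were cell cycle (4 of 10 fell, adjusted p = 0.181), glycolysis (2 of 15 fell and 1 rose, adjusted p = 0.128), heat shock (2 of 11 rose and 2 fell, adjusted p = 0.716) and immediate early genes (4 of 11 rose and 1 fell, adjusted p = 0.0893), of which Arc was 83.2 times higher in summed counts (interval 22.6 to 694). The class lay in cluster 9 at P5, clusters 9 and 13 at P10, and the same clusters with more cells in 13 at P16 and P21. Cluster 13, with Tmem2 as its first top gene, held 4 cells at P5 and 439 at P21. A change in the makeup of this class is therefore not separated from a change within its cells.

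Oligodendrocyte-like cells, with 3 cells at P5, were compared between P21 and P10, a comparison chosen after seeing the data. The cell adhesion gene Cntn2 (chromosome 1, 132509427 to 132543256), which organises the axon beside the node of Ranvier, rose by 6.75 ± 0.40, from 2.63 ± 3.04 to 403 ± 9.60 CPM, and Efhd1 by 5.38 ± 0.37. Ptgds, Klk6 and Hcn2 were 64.5 (interval 17.8 to 533), 52.4 (interval 14.5 to 433) and 34.5 (interval 11.8 to 168) times higher in summed counts. Fam181b fell by 4.59 ± 0.28, Alox5 by 4.0 ± 0.32, Il23a by 3.15 ± 0.44, Lsamp by 2.97 ± 0.22 and Man1c1 by 2.78 ± 0.31. Of 9783 genes 1777 changed, 972 higher and 805 lower at P21. The count was 1088 without P10 sample 1, 1083 without P10 sample 2 and 658 with the pairs summed.

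Of 14 immediate early genes 12 rose in oligodendrocyte-like cells (12 adjusted over the list alone, median 2.71, adjusted p = 9.6e-14). Fos rose by 5.05 ± 0.40 and Jund by 2.28 ± 0.21. Summed, the list rose by 1.62 log2 units in free RNA. Of 13 myelin genes 8 rose and 2 fell (10 adjusted over the list alone, median 0.75, adjusted p = 0.000555). Mal rose by 2.80 ± 0.26 and Opalin by 1.93 ± 0.22, and the list had adjusted p = 0.108 with an estimated correlation. Of 10 cell cycle genes 2 fell (3 adjusted over the list alone, median -0.57, adjusted p = 0.0183), and the list had adjusted p = 0.151 with an estimated correlation. Not called were cholesterol synthesis (1 of 16 rose and 2 fell, Lss by 1.00 ± 0.19, adjusted p = 0.483), ribosomal proteins (0 of 27 called, adjusted p = 0.364), glycolysis (1 of 15 rose and 1 fell, adjusted p = 0.985), heat shock (1 of 12 rose, Hsp90ab1 by 0.84 ± 0.24, adjusted p = 0.847) and respiratory chain (1 of 22 rose, Uqcrh by 0.59 ± 0.19, adjusted p = 0.985). The class lay in cluster 7 at P10 and mainly in clusters 3 and 7 at P16 and P21. Cluster 3 held 13 cells at P10 and 2826 at P21. A change in makeup is thus not separated from a change within oligodendrocyte-like cells.

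Microglia-like cells of P21 carried more transcripts of surveying microglia and fewer of dividing ones. Cst3, a protease inhibitor (chromosome 2, 148871722 to 148875692), rose by 2.85 ± 0.18, from 3240 ± 298 to 23850 ± 5200 CPM, Pmp22 by 2.94 ± 0.40, Socs3 by 2.67 ± 0.35, Fam134b by 3.06 ± 0.77 and the inflammasome gene Nlrp3 by 2.63 ± 0.54. Top2a, a topoisomerase of dividing cells, fell by 3.16 ± 0.54, Sh3bgrl by 3.17 ± 0.52 and Rrm2 by 3.17 ± 0.67, and Cdk1 and Tk1 were 16.4 (interval 4.43 to 137) and 13.3 (interval 4.44 to 65.0) times lower in summed counts. Apoe, a lipid carrier, fell by 2.81 ± 0.38, from 6977 ± 2169 to 1045 ± 723 CPM. Of 3862 genes 580 changed, 285 higher and 295 lower at P21. The count was 298 without P21 sample 2 and 77 with the pairs summed, when Fam134b, Nlrp3 and Rrm2 were not called (adjusted p of 0.231, 0.153 and 0.0688).

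Of 16 homeostatic microglia genes 8 rose and 0 fell (10 adjusted over the list alone, median 0.67, adjusted p = 5.0e-07). Selplg rose by 1.90 ± 0.24 and Sparc by 1.36 ± 0.15. Of 15 cell cycle genes 13 fell (13 adjusted over the list alone, median -3.04, adjusted p = 3.9e-06). Mcm2 fell by 3.04 ± 0.56, with Mcm5 36.7 times lower in summed counts (interval 6.47 to 1460). Of 15 immediate early genes 6 rose (11 adjusted over the list alone, median 0.93, adjusted p = 4.0e-06). Btg2 rose by 1.42 ± 0.27 and Nr4a1 by 0.90 ± 0.24. Summed, the list rose by 1.54 log2 units in free RNA. Of 13 genes of early postnatal activated microglia 5 fell (5 adjusted over the list alone, median -0.62, adjusted p = 0.0166). Lpl fell by 1.45 ± 0.37, and the list had adjusted p = 0.344 with an estimated correlation and 0.0615 without the genes that could be free RNA. Of 16 complement and phagocytosis genes 5 rose and 1 fell (8 adjusted over the list alone, median 0.44, adjusted p = 0.00109). Mertk rose by 1.62 ± 0.28 and Itgam by 0.93 ± 0.23, and the list had adjusted p = 0.125 with an estimated correlation. Of 5 antigen presentation genes 2 rose (3 adjusted over the list alone, median 0.69, adjusted p = 0.0160). H2-K1 rose by 1.65 ± 0.37, and the list had adjusted p = 0.21 with an estimated correlation. Of 27 ribosomal protein genes 9 fell (10 adjusted over the list alone, median -0.29, adjusted p = 1.2e-05). Rpl3 fell by 0.91 ± 0.18, and the list had adjusted p = 0.206 with an estimated correlation. Of 21 respiratory chain genes 6 fell (7 adjusted over the list alone, median -0.46, adjusted p = 6.4e-05). Uqcrq fell by 1.62 ± 0.32, and the list had adjusted p = 0.125 with an estimated correlation. Glycolysis (1 of 9 rose, adjusted p = 0.725) and heat shock (1 of 11 rose, adjusted p = 0.668) were not called. Of 25 called list members that the rule names in this class 7 were called with the pairs summed. Oligodendrocyte genes took 0.0519% ± 0.00621 of UMIs at P5 and 1.62% ± 1.36 at P21.

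Macrophage-like cells gained the adhesion gene Vcam1 (chromosome 3, 116109949 to 116129688), by 3.72 ± 0.55, from 24.8 ± 8.51 to 417 ± 195 CPM, Sult1a1 by 3.16 ± 0.67, the growth factor gene Hbegf by 2.74 ± 0.56, Scoc by 2.35 ± 0.56 and Jund by 2.28 ± 0.39. Eef1g, an elongation factor, fell by 2.45 ± 0.53 and H2afv by 2.58 ± 0.77. Top2a, with 0 counts at P21, was at least 9.58 times lower (floor of 3 counts over the age), AU022252 7.78 times (interval 2.58 to 38.4) and Pdap1 6.88 times (interval 1.82 to 58.2). Of 1463 genes 146 changed, 59 higher and 87 lower at P21, with 96, 89 and 95 without P5 samples 1, 2 and 3 and 92 and 95 without P21 samples 1 and 4. Of the 10 genes named here 4 (H2afv, Top2a, AU022252 and Pdap1) lost their call when some 1 sample was left out. With the pairs summed 1 gene, Vcam1, was called, and 399 had an unadjusted p under 0.05.

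Of 26 ribosomal protein genes 15 fell in macrophage-like cells (22 adjusted over the list alone, median -1.03, adjusted p = 8.3e-15). Rpl14 fell by 1.89 ± 0.38. Of 16 immediate early genes 4 rose (5 adjusted over the list alone, median 0.93, adjusted p = 2.9e-05). Fosb rose by 2.14 ± 0.36. Of 5 antigen presentation genes 1 rose, Bst2 by 1.39 ± 0.31 (3 adjusted over the list alone, median 1.02, adjusted p = 0.00655). Respiratory chain, with 0 of 13 members called (0 adjusted over the list alone), was lower as a list (median -0.69, adjusted p = 0.00426), and the list had adjusted p = 0.113 with an estimated correlation. Complement and phagocytosis, with C1qb of 14 up by 0.89 ± 0.26 (1 adjusted over the list alone, median 0.30, adjusted p = 0.0251), had adjusted p = 0.113 with an estimated correlation. Early activated genes (2 of 11 rose, Apoe by 0.85 ± 0.23, and Lgals1 fell by 1.72 ± 0.43, adjusted p = 0.0544) and heat shock (0 of 11 called, adjusted p = 0.395) were not called. Oligodendrocyte genes took 0.0879% ± 0.0149 of UMIs at P5 and 2.36% ± 1.81 at P21.

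In endothelial-like cells genes of antigen presentation and the interferon response rose as a list, and single transporters rose or fell. Slco1a4, an organic anion transporter (chromosome 6, 141805440 to 141856199), rose by 3.26 ± 0.17, from 302 ± 25.3 to 2644 ± 180 CPM, Slc2a1, the glucose transporter, by 2.31 ± 0.40 and the efflux pump Abcb1a by 2.09 ± 0.17. Sema3c rose by 4.38 ± 0.21, Ndrg1 by 4.19 ± 0.24, Itih5 by 3.98 ± 0.43, Ndnf by 3.88 ± 0.25 and the smooth muscle actin Acta2 by 6.16 ± 1.11. Acta2 was the first top gene of the smooth muscle-like cluster. That class had no gene test, so the free RNA limit for named genes did not compare Acta2 with it. RNA of smooth muscle-like cells is therefore not excluded as its source. The amino acid transporters Slc1a4 and Slc7a8 fell by 5.33 ± 0.41 and 4.4 ± 0.51, Mfap2 by 3.47 ± 0.33, the chemokine receptor Cxcr4 by 3.37 ± 0.48 and Fkbp10 by 2.61 ± 0.33. Of 8967 genes 1841 changed, 1004 higher and 837 lower at P21, and 413 with the pairs summed.

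All 12 antigen presentation and interferon genes rose in endothelial-like cells (12 adjusted over the list alone, median 1.88, adjusted p = 1.1e-12), among them Isg15 by 2.49 ± 0.27, Ifit1 by 4.37 ± 0.53 and B2m by 1.46 ± 0.17. Of 16 immediate early genes 11 rose (14 adjusted over the list alone, median 1.19, adjusted p = 9.0e-10). Klf4 rose by 2.17 ± 0.20 and Atf3 by 2.15 ± 0.23. Of 18 cell cycle genes 14 fell (14 adjusted over the list alone, median -1.89, adjusted p = 2.5e-07). Cdk1 fell by 2.34 ± 0.32. Of 16 blood-brain barrier genes 7 rose and 3 fell (11 adjusted over the list alone, median 0.63, adjusted p = 0.00359). Of 27 ribosomal protein genes 6 fell (6 adjusted over the list alone, median -0.23, adjusted p = 0.00133), and the list had adjusted p = 0.596 with an estimated correlation. Not called were angiogenesis (4 of 14 rose, Flt1 by 1.41 ± 0.18, and 5 fell, Plxnd1 by 1.11 ± 0.17, adjusted p = 0.896), basement membrane (2 of 13 rose, Itga6 by 1.95 ± 0.18, and 4 fell, Nid1 by 1.5 ± 0.21, adjusted p = 0.478), glycolysis (1 of 15 fell, adjusted p = 0.941), heat shock (3 of 12 rose, Hspb1 by 2.67 ± 0.41, adjusted p = 0.0591) and respiratory chain (1 of 22 rose, adjusted p = 0.725). Oligodendrocyte genes took 0.116% ± 0.0182 of UMIs at P5 and 0.584% ± 0.0842 at P21. The class lay in cluster 12 at P5 and mainly in cluster 4 at P16 and P21, so a change in its makeup is not separated from a change within its cells.

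Pericyte-like cells, which wrap capillaries, gained Ackr3, a chemokine receptor, by 4.29 ± 0.27, Casq2 by 4.06 ± 0.31, Klf9 by 4.01 ± 0.30 and Serpini1 by 3.70 ± 0.57. The matrix protease Mmp9, with 0 counts at P21, was at least 22.4 times lower (floor of 3 counts over the age), and Hn1, Cenpa and Srgap1 were 35.3 (interval 6.30 to 1399), 17.8 (interval 3.16 to 707) and 17.6 (interval 3.12 to 699) times lower in summed counts. Of 4026 genes 600 changed, 310 higher and 290 lower at P21. The count was 382 without P21 sample 1 and 162 with the pairs summed.

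Of 27 ribosomal protein genes 15 fell in pericyte-like cells (17 adjusted over the list alone, median -0.92, adjusted p = 6.2e-12). Rpl23 fell by 1.38 ± 0.20, and the list had adjusted p = 0.107 with an estimated correlation. Of 15 immediate early genes 8 rose and 1 fell (11 adjusted over the list alone, median 1.15, adjusted p = 8.4e-09). Fosb rose by 2.36 ± 0.26. Of 13 cell cycle genes 7 fell (9 adjusted over the list alone, median -1.74, adjusted p = 0.000233), among them Ube2c. Of 12 heat shock genes 4 rose (6 adjusted over the list alone, median 0.77, adjusted p = 0.000581). Hspb1 rose by 2.84 ± 0.31. Each of these 3 lists had adjusted p = 0.0752 with an estimated correlation. Basement membrane (4 of 14 rose, Lamb2 by 1.75 ± 0.24, and 6 fell, Nid2 by 2.41 ± 0.38, adjusted p = 0.431), glycolysis (0 of 12 called, adjusted p = 0.743) and respiratory chain (0 of 22 called, adjusted p = 0.0884) were not called.

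Over the 8 classes compared between P21 and P5, 47 list tests passed, 23 of them with an estimated correlation, and 50 passed with the pairs summed. Of the called list members that the rule names, those called with the pairs summed were 42 of 45 in excitatory neuron-like, 22 of 27 in astrocyte-like, 12 of 17 in committed oligodendrocyte-like, 6 of 11 in oligodendrocyte-like (P21 and P10), 18 of 26 in endothelial-like and 13 of 15 in pericyte-like cells, and none of 12 in macrophage-like cells, where edgeR called 1 gene in all. When some 1 sample was left out, calls of such members were lost for 2, 2, 2, 4, 3, 2 and 5 genes in these classes, for 6 of 17 in OPC-like and for 5 of 25 in microglia-like cells, among them Mcm5 (OPC-like), Lpl (microglia-like), Apoe, C1qb and Lgals1 (macrophage-like) and Uqcrh and Hsp90ab1 (oligodendrocyte-like). Of the largest changes outside macrophage-like cells Hes5 (OPC-like), Ptgds (oligodendrocyte-like), Nr4a1 (astrocyte-like, P10 and P5) and Mgst1, Aacs and Kcnq3 (astrocyte-like, P21 and P16) lost theirs. Cytosolic ribosomal protein genes were lower in all 8 of these classes, and immediate early genes were higher in OPC-like, microglia-like, macrophage-like, endothelial-like and pericyte-like cells and lower in astrocyte-like cells. With an estimated correlation the ribosomal list did not pass in excitatory neuron-like, committed oligodendrocyte-like, microglia-like, endothelial-like and pericyte-like cells, nor the immediate early list in OPC-like, pericyte-like and astrocyte-like cells.

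**Figure D4:**
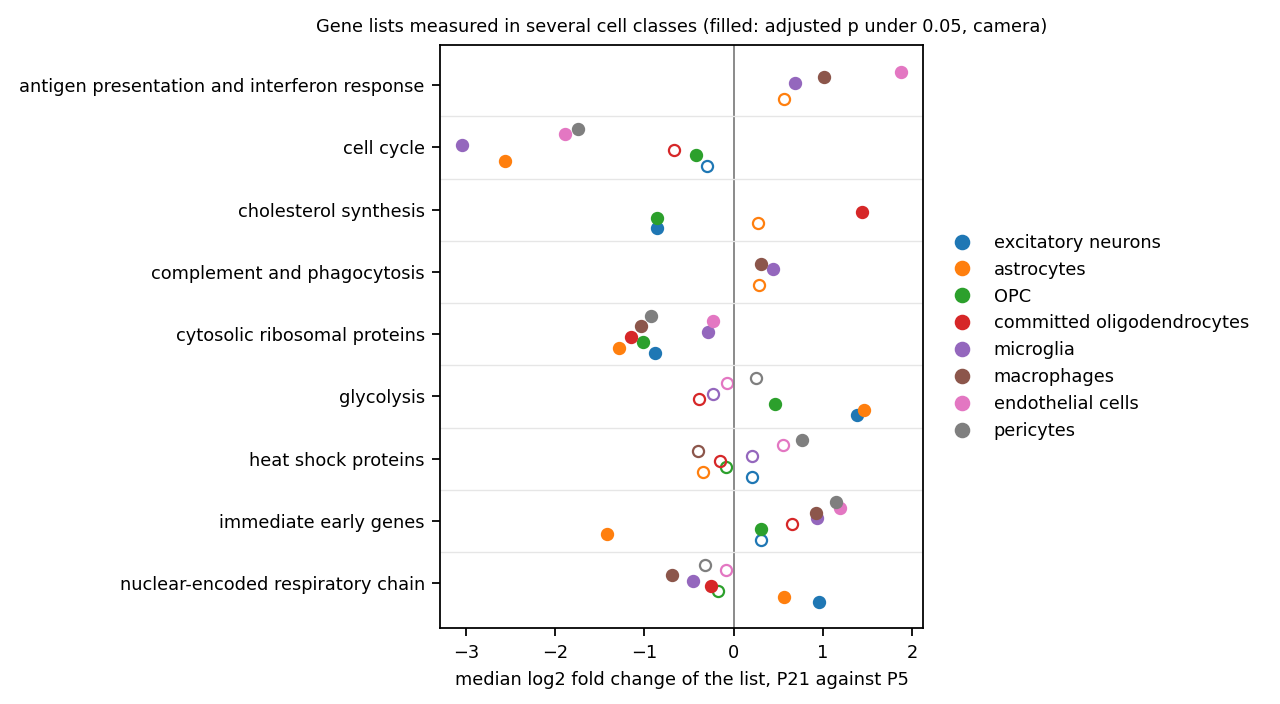
Median log2 fold change between P21 and P5 (x axis) of gene lists measured in several classes (y axis), 1 point per class and list. Filled points have an adjusted p under 0.05 in the camera test with a preset correlation; the ribosomal protein points all lie below 0.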

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

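The tests of pools by Xist and of sequencing runs for the sample pairs, those of differences between classes and that of the most that free RNA can make up of a class were chosen only after the result was seen. In 8 of 234 groups of 4 samples the highest or lowest sample lay further from the rest than Dixon's 95% critical value allows, and chance alone gives about 1 group in 20. These were the endothelial-like share in P21 sample 2, 19.2% against 8.22% to 9.53% in the others, and CPM of St8sia2 in excitatory neuron-like cells in P21 sample 3 (1.41, the others 0), Vim in astrocyte-like cells in P21 sample 4 (87.0 against 27.6 to 32.9), Nr4a1 in astrocyte-like cells in P5 sample 3 (1444 against 1605 to 1625), Apoe in macrophage-like cells in P21 sample 1 (14790 against 19450 to 20390), Sema3c in endothelial-like cells in P21 sample 4 (391 against 328 to 332), Slc1a4 in endothelial-like cells in P21 sample 3 (0 against 13 to 13.5) and Ackr3 in pericyte-like cells in P21 sample 3 (642 against 1122 to 1192). The denominator of the endothelial-like share holds cells with the profile of free RNA, 53.45%, 9.16%, 5.27% and 0.5% of P21 samples 1 to 4. The distance of sample 2 from sample 1 in this share is not separated from that difference.

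Between classes, differences in the change of a list from P5 to P21 were tested (camera on the difference, with an estimated correlation) for 13 combinations picked because the list had been called in opposite directions. Adjusted over these 13 alone, 11 passed. Over all 172 combinations of a list and 2 classes 0 passed, where 43 had an unadjusted p under 0.05, and with the pairs summed 0 passed, where 12 had one. The differences below are therefore not established. Cholesterol synthesis genes moved higher in committed oligodendrocyte-like cells than in excitatory neuron-like cells (median difference 2.44, adjusted p = 0.0179) and than in OPC-like cells (2.10, adjusted p = 0.00713). Immediate early genes moved higher than in astrocyte-like cells in microglia-like (2.16, adjusted p = 0.0129), macrophage-like (1.53, adjusted p = 0.0173), endothelial-like (2.14, adjusted p = 0.0161) and pericyte-like cells (2.11, adjusted p = 0.0161). The respiratory chain moved higher in excitatory neuron-like cells than in committed oligodendrocyte-like (1.09, adjusted p = 0.0366), microglia-like (1.78, adjusted p = 0.00713) and macrophage-like cells (1.68, adjusted p = 0.00937), and higher in astrocyte-like than in microglia-like (1.04, adjusted p = 0.0161) and macrophage-like cells (1.34, adjusted p = 0.0277). Immediate early genes in OPC-like against astrocyte-like cells (1.33, adjusted p = 0.0516) and the respiratory chain in astrocyte-like against committed oligodendrocyte-like cells (0.95, adjusted p = 0.0963) did not pass.

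Barcodes above 15000 UMIs with a mitochondrial share of at most 20%, which entered 1 alternative and no other comparison, numbered 1672 at P5, 520 at P10, 108 at P16 and 10 at P21. Of these 91.1%, 95.6%, 92.6% and 70% were nearest to the excitatory neuron-like profile.

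The first pattern weighed is that samples 1 and 2, and samples 3 and 4, of an age resemble each other. Droplets counted under both samples of a pair are argued against as the whole cause: 5036 barcodes occurred in both samples of a pair where 864 were expected, but without them the chi-square between pairs in excitatory neuron-like cells was still at least 1.73 times that within pairs at every age. Over the other classes compared the lowest such ratio was 1.49, in OPC-like cells at P21. These barcodes were named alike in 61.1% to 95.9% of cases, where chance gives 14.7% to 46.4%, so droplets appear to have been counted in both samples. They hold 16.4% of cells, predicted doublets included, and the cell numbers given include them. A candidate explanation is that a pair holds libraries of 1 pool, since Xist, which follows the sex of the animals, differed less within pairs than between them in 4 of 4 ages. Sequencing runs stay open, since 12 libraries are tied to no sample. No biological explanation was tested.

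The second pattern is the lower level of cytosolic ribosomal protein genes at P21. In free RNA the summed list fell by 1.35, and in 0 of 8 classes did the fall exceed this by more than the SD between samples. Free RNA brings the abundant transcripts of neurons, astrocytes and oligodendrocytes with it, so the level of those of another lineage limits its share of a class (upper 95% counting limit). Of the 8 classes, 7 had levels possible at P5 and at P21 within this limit that lay apart. Free RNA is argued against as the whole cause in 6 of them, astrocyte-like, OPC-like, committed oligodendrocyte-like, macrophage-like, endothelial-like and pericyte-like cells, by a ratio of at least 1.21. It stays open in excitatory neuron-like and microglia-like cells, of which 1 of 2, microglia-like cells, lay apart, by a ratio of 1.03 only. In 2 versions of this limit tried before it, without counting error, the levels lay apart in 7 of the 8 classes with the same lists and in 8 with every marker list, which adds lists of few counts. Whether a difference between sequencing runs accounts for it cannot be told, since no P5 or P21 sample is tied to a run. From P10 to P16 within the samples of the first 2 runs the median was at or below -0.2 in 3 of 8 classes. These medians ran from -0.828 (astrocyte-like) to 0.244 (macrophage-like). In the other P10 and P16 samples they ran from -1.18 (committed oligodendrocyte-like) to -0.119 (microglia-like). No conclusion on runs is drawn from this step. Age itself stays open as untested.

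The third pattern is the higher level of immediate early genes at P21 in 6 classes that are not neurons. In free RNA the summed list rose by 1.54 against P5 and by 1.62 against P10, and in 1 of 6 classes, oligodendrocyte-like cells, the rise, 2.12, exceeded it by more than the SD between samples. In the other classes the list rose by 0.919 to 1.16, less than in free RNA. Within the limit above, free RNA is at most 26.6% of a class. The levels possible at the early age and at P21 then lay apart in 6 of 6 classes. The same held in the 2 other versions of the limit. Free RNA is argued against as the whole cause in OPC-like, oligodendrocyte-like, microglia-like, endothelial-like and pericyte-like cells, by a ratio of at least 1.21. It stays open in macrophage-like cells, with a ratio of 1.1. Counting error of the list itself does not enter these ratios. Handling that differed between pools could not be told apart from age, with 14 of 23 class and age combinations on the side of the majority of their age where random signs give a mean of 15.2 (exact one-sided p = 0.886). The rule fixed beforehand counts a number no larger than this mean against handling, and 14 meets it. A stricter rule was used here, which asks for a number below the mean by more than its SD, 1.5. The number 14 did not meet the stricter rule. Age itself stays open as untested.

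Each gene count was compared with the 35 splits of the same 8 samples, and chance can be excluded where the real split alone gave so many, if the 8 samples are independent. If each pair is 1 pool, only 3 of the 35 splits keep the pairs whole, too few for a share under 0.05. The real split alone gave so many for excitatory neuron-like cells (P21 and P5, 5399, highest other split 0; P10 and P5, 1864 and 445; P16 and P10, 3441 and 1080; P21 and P16, 932 and 14), for astrocyte-like cells (P21 and P5, 2629 and 1; P10 and P5, 571 and 154; P16 and P10, 1371 and 633), and for OPC-like (1558 and 0), committed oligodendrocyte-like (3083 and 0), oligodendrocyte-like (1777 and 13), microglia-like (580 and 0), macrophage-like (146 and 2), endothelial-like (1841 and 0) and pericyte-like cells (600 and 1). For astrocyte-like cells between P21 and P16, 2 of the 35 splits gave as many, 40 in the real split and 55 in the other, so chance cannot be excluded. The highest other split kept the pairs whole in all 6 comparisons of successive ages and in oligodendrocyte-like cells, which points to a structure of the samples. For the lists the real split gave 47 calls and the highest other 45, from a split with 1 P5 sample and 3 P21 samples on a side, while 18 splits with equal numbers of each age per side gave 1 to 21.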

How the results depend on the processing

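The sums of pairs, the fits with 1 pair per age, the addition of barcodes above 15000 UMIs and the oligodendrocyte-like comparison of P21 and P10 were chosen only after the data were seen. Outside the omission of single samples, 7 results on class shares became stronger (those with the pairs summed or the replicate block, with smallest possible p-values of 0.333 and 0.125, say nothing about stability), 147 of 192 gene counts stayed within 1.5 times and 45 moved, 496 of 544 list results stayed the same, 16 became stronger, 31 weaker and 1 reversed, and of 4765 results on named genes 4429 stayed the same, 141 became stronger, 194 weaker and 1 reversed. With the pairs summed, which leaves 2 samples per age, the counts were 3430, 193, 1201 and 43 in excitatory neuron-like cells (P21 and P5, P10 and P5, P16 and P10, P21 and P16), 1300, 42, 398 and 0 in astrocyte-like cells (edgeR; for the last, 507 at an unadjusted p under 0.05, and 102 by DESeq2 on the 16 samples), 397 in OPC-like, 1628 in committed oligodendrocyte-like, 658 in oligodendrocyte-like, 77 in microglia-like, 1 in macrophage-like, 413 in endothelial-like and 162 in pericyte-like cells. With a covariate for the samples named in the first 2 runs, samples 1 and 2 of P10 and of P16, they were 3360 (excitatory neuron-like, P10 and P5), 1981 (P21 and P16), 1597 (astrocyte-like, P10 and P5), 440 (P21 and P16), 926 (microglia-like) and 244 (macrophage-like). If each pair is 1 pool, the fits with 1 pair per age hold 1 pool per age. Differences between pools then do not enter their counts. With samples 1 and 2 only the counts were 4208, 6127 and 2036 for the 3 steps in excitatory neuron-like cells, 753 in astrocyte-like cells between P21 and P16, 2405 in OPC-like, 3336 in oligodendrocyte-like, 1200 in microglia-like, 2883 in endothelial-like and 985 in pericyte-like cells. With samples 3 and 4 only they were 4446 (P10 and P5) and 2500 (P21 and P16) in excitatory neuron-like cells, 1032, 2022 and 354 in astrocyte-like cells (P21 and P5, P10 and P5, P21 and P16), 945 in OPC-like, 961 in oligodendrocyte-like, 191 in microglia-like and 270 in pericyte-like cells. Without the gene filter they were 164 in astrocyte-like cells between P21 and P16, 957 in microglia-like and 306 in macrophage-like cells. The astrocyte-like count between P21 and P16 was also 102 with DESeq2, 73 with only these ages in the fit and 144 with the replicate block. With the neurons out of the denominator 7 of 12 classes passed, with differences of -20.9 (OPC-like), -21.5 (astrocyte-like), 3.28 (committed oligodendrocyte-like), -3.36 (fibroblast-like), -0.666 (macrophage-like), 47.2 (oligodendrocyte-like) and -4.77 percentage points (pericyte-like). With an estimated correlation 23 of the 47 list calls passed. The list of GABA-A receptors reversed in excitatory neuron-like cells under fry, which called it higher (adjusted p = 0.00578, with a median of -0.35 and a mean of 0.09), where camera had it lower and not called (adjusted p = 0.974), and Hspd1 reversed there with samples 1 and 2 only (-0.0029, adjusted p = 0.988). Leaving out 1 sample at a time gave 4858 to 5048, 1278 to 1860, 2831 to 3559 and 570 to 785 genes in excitatory neuron-like cells, 1906 to 2561, 319 to 721, 1135 to 1303 and 14 to 51 in astrocyte-like cells, 952 to 1447 in OPC-like, 2666 to 2972 in committed oligodendrocyte-like, 1083 to 1895 in oligodendrocyte-like, 298 to 586 in microglia-like, 89 to 110 in macrophage-like, 1390 to 1597 in endothelial-like and 382 to 585 in pericyte-like cells, and 45 to 50 list calls. Counts moved by over 1.5 times without P16 sample 3 (570, excitatory neuron-like, P21 and P16), P10 sample 3 or 4 (352 and 319, astrocyte-like, P10 and P5), P21 sample 1, P21 sample 2 or P16 sample 3 (14, 20 and 24, astrocyte-like, P21 and P16), P21 sample 2 (952, OPC-like, and 298, microglia-like), P10 sample 1 or 2 (1088 and 1083, oligodendrocyte-like), P5 samples 1, 2 and 3 and P21 samples 1 and 4 (96, 89, 95, 92 and 95, macrophage-like) and P21 sample 1 (382, pericyte-like). The cause was not tested for any of these. A minimum of 1000 UMIs per cell was not run for microglia-like, macrophage-like and pericyte-like cells, and in simulated data 13.7% of genes changed by 1 log2 unit were recovered in microglia-like cells and 52% in excitatory neuron-like cells, where depth and dispersion were not separated.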
